A study of Mus musculus with 10 samples.

How the data were processed

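Polyadenylated RNA of 2/20 CTLs was measured at rest, 4 h and 24 h after AH1 peptide, and 4 h and 24 h into co-culture with 4T1 cells, with 2 libraries in each of 5 groups. The line was maintained with AH1 peptide at 1 µg/mL, IL-2 at 10 units/mL and irradiated BALB/c spleen cells, and whether spleen cells were present during the peptide activation is not given in the sources used here. Per the submitters, CTLs were taken with magnetic beads carrying an antibody to CD45 before RNA extraction, and stranded libraries were made from poly(A) RNA. No library of 4T1 cells alone was available. What kind of replicates the 2 libraries of a group are is not given either.

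The values are read counts per Ensembl gene as deposited by the authors. They are whole numbers without scaling. The submitters' processing notes name DESeq2 1.36 and the mouse build mm10. The aligner, the counting tool, the strand setting and the treatment of reads shared by genes are not given in the sources used here. Levels of genes with close paralogs, such as Oas1a, Gbp4, Acta1 and Igkc, and of genes that overlap others depend on that treatment. The file held 35275 genes, of which 12534 had no count in any library. Of the gene identifiers, 34490 are in GENCODE mouse release 21 and 24932 have the same coordinates there. Positions are those deposited.

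Library totals ran from 14104658 to 22910633 counts. In the peptide 4 h libraries Ifng alone took 9.14% and 7.48% of the counts, and their TMM factors were 0.711 and 0.758 against 1.03 to 1.11 in the other libraries. Libraries of one group were not duplicates of each other, since the mean chi-square per gene with at least 20 counts was 6.94 at rest, 28.3 and 21 with peptide at 4 h and 24 h, and 12.6 and 47.7 in co-culture. The difference between replicates followed GC content to a varying degree (Spearman correlation 0.144 at rest, -0.472 and 0.360 with peptide, -0.198 and 0.515 in co-culture, over 99.8% of 8669 genes).

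Genes were tested with edgeR 4.0.16 in R 4.3.3. Genes with enough counts by filterByExpr were kept (14729), libraries were scaled by TMM, and a quasi-likelihood model with a mean for each group and no covariate was fitted to all 10 libraries. The common biological coefficient of variation was 0.159, with 5 residual degrees of freedom and a prior of 7.82. In all, 9 contrasts were tested two-sided: each activated group against rest, co-culture against peptide at each time, 24 h against 4 h for each source, and the interaction of source and time. P-values were adjusted by the Benjamini-Hochberg method within each contrast, with a threshold of 0.05. The model assumes that the spread of each gene is shared by the groups.

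A set of 29 gene lists with 633 symbols was fixed before the data were examined, as were the contrasts, the tests, the rule for naming genes and the alternatives, apart from those said below to have been added. Of these symbols 3 were not found. The lists covered amino acid transporters, tryptophan and aryl hydrocarbon receptor genes, cytosolic aminoacyl-tRNA synthetases, integrated stress response genes, serine and one-carbon metabolism, cytotoxic effectors, cytokines and chemokines, early T cell receptor response genes, activation receptors, inhibitory receptors, memory genes, cell cycle, ribosome biogenesis, glycolysis, oxidative phosphorylation, cholesterol synthesis, type I interferon and interferon-gamma responses, hypoxia, TGF-beta response, p53 and apoptosis, heat shock, and T cell identity, and markers of epithelial, stromal, B, myeloid, CD4 T and NK, and erythroid cells. Lists were tested with camera in limma 3.58.1 on log2 CPM (prior count 2, preset correlation between genes 0.01), adjusted over the lists of a contrast, and again with the correlation estimated for each list. Members past the threshold are counted with adjustment over all genes and with adjustment over the list alone. Camera compares a list with the other genes, whereas fry, used as an alternative, tests whether the genes of a list move one way on balance.

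Genes named in the text were Slc7a5 and Slc3a2, the 5 highest and 5 lowest fold changes past the threshold with groups that did not overlap and at least 5 CPM in the higher group, up to 4 members of a list per direction by p-value, and a panel of 25 genes. Gene models without a name and immunoglobulin and T cell receptor segments were left out of the highest and lowest. Not all genes that the rule allows are named, and some results are not reported here. In the 8 contrasts of groups, 224 of 224 named results past the threshold had both libraries of one group beyond both of the other. Chance gives this separation 16.7% of the time in a direction fixed beforehand, whereas the direction here was that of the observed fold change. Part of the rule requires the separation and the results had passed the threshold, so it is no further evidence for the calls. Folds against a group without counts were computed against 3 counts over the group, and ratios with 1 to 3 counts carry a 95% interval from counting.

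Alternatives were DESeq2 1.42.0 with its own size factors and filter, DESeq2 size factors in edgeR, library totals alone, no count filter, a minimum of 1 CPM in 2 libraries, only the groups compared, the replicate number as a block, glmTreat against a log2 fold change of 1, and each library left out in turn. DESeq2 thus changed several choices together, and fits on fewer libraries also changed the genes tested. Chosen after seeing the data were a fit without the 4 co-culture libraries and the T cell identity scaling, which sets factors from the median of T cell identity genes with a mean of at least 10 CPM. The second gives changes per T cell identity transcript.

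The procedure was tested on simulated data with these library sizes and spreads, with 200 genes changed. It recovered 66.7% to 83.3% of changes of 4-fold, 25.4% to 53.7% of 2-fold and 0% to 14.9% of 1.5-fold, with 5.75% to 12.5% of calls false. Camera found a planted list in all 9 contrasts with 0 other lists called. Genes were drawn independently of each other there, so the preset correlation between genes was not tested. Genes called in both peptide and co-culture against the same resting libraries were set beside 20 simulations of unchanged groups. With 2 libraries per group, no test of single outlying libraries and no test of other splits of the samples was made. All sample columns were used.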

Results

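Polyadenylated RNA was sequenced from 2/20 cells, a mouse cytotoxic T lymphocyte (CTL) line specific for the AH1 peptide. The line was sampled at rest, 4 h or 24 h after activation with AH1 peptide, and 4 h or 24 h into co-culture with 4T1 cells, a mammary carcinoma line from BALB/c mice. Each of these 5 groups had 2 libraries, and the 10 libraries held 14104658 to 22910633 gene counts. Levels are given as CPM, counts scaled to the effective size of each library, as mean ± SD with n = 2, and log2 fold changes carry ± SE. Adjusted p-values are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over 14729 genes, and a gene is said to have risen or fallen where its adjusted p was under 0.05. They measure the spread between 2 libraries of a group, which may be technical rather than biological.

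The series title concerns tryptophan uptake through Slc7a5, so this transporter and its partner were followed in all comparisons. Slc7a5 (ENSMUSG00000040010, chromosome 8, minus strand, 121881150 to 121907694, mm10) is the light chain of the LAT1 carrier of large neutral amino acids. Slc3a2 (ENSMUSG00000010095, chromosome 19, minus strand, 8706882 to 8723369, mm10) is its heavy chain, also known as CD98. Slc7a5 stood at 14.7 ± 1.91 CPM at rest (SD, n = 2), at 285 ± 57.2 and 213 ± 38.6 CPM with peptide at 4 h and 24 h, and at 101 ± 14.3 and 86.5 ± 35.9 CPM in co-culture at 4 h and 24 h. The 8 activated libraries lay at 61.1 CPM or more, above both resting libraries. Slc3a2 stood at 109 ± 10.4 CPM at rest, 458 ± 61.1 and 182 ± 17.2 CPM with peptide, and 176 ± 19.3 and 128 ± 26.6 CPM in co-culture.

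**Figure D1:**
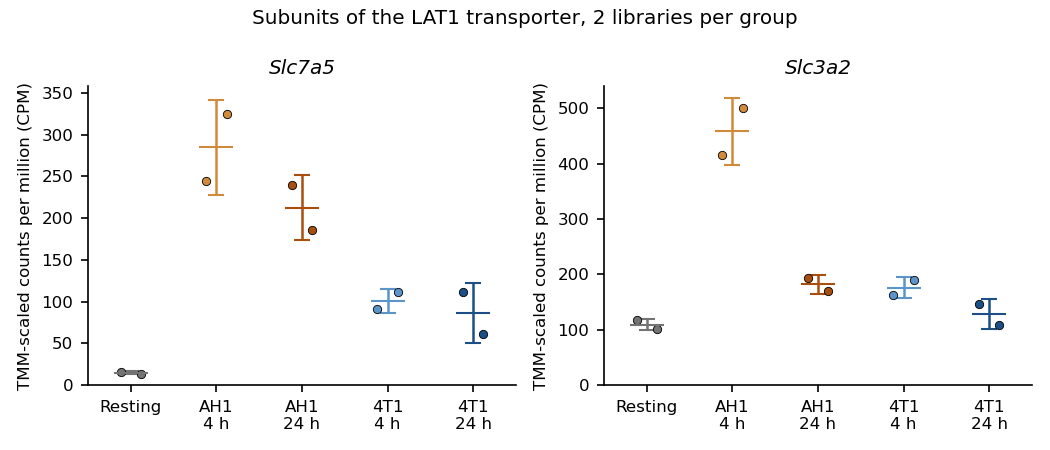
CPM of Slc7a5 and Slc3a2 on linear axes in the 5 groups, with points for single libraries and bars for mean ± SD (n = 2). Slc7a5 averaged 14.7 CPM at rest, 285 and 213 CPM with peptide at 4 h and 24 h, and 101 and 86.5 CPM in co-culture, and the difference of co-culture from peptide changed sign at both times with T cell identity scaling.

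The co-culture libraries held transcripts of epithelial cells at high levels, and parts of each comparison with them are also given under a second scaling. Krt8, a keratin of simple epithelia, averaged 1306 ± 71.1 and 931 ± 108 CPM in co-culture at 4 h and 24 h against 1.43 ± 0.598 CPM at rest (SD, n = 2). The second scaling, chosen after seeing the data, sets libraries equal on the median of the T cell identity genes, a list of T cell receptor complex and proximal signaling genes. It gives changes per T cell identity transcript and does not remove RNA of other cells. In co-culture it raises all genes of a library alike, those of 4T1 cells included. The median of all genes at 24 h of co-culture against rest went from 0.05 to 2.63 with it. It also assumes that these T cell genes did not themselves change. Without a library of 4T1 cells alone, rises in co-culture, those of Slc7a5 and Slc3a2 included, were not assigned to CTLs or 4T1 cells. In the plot of marker levels the keratins and the T cell genes are shown side by side.

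**Figure D2:**
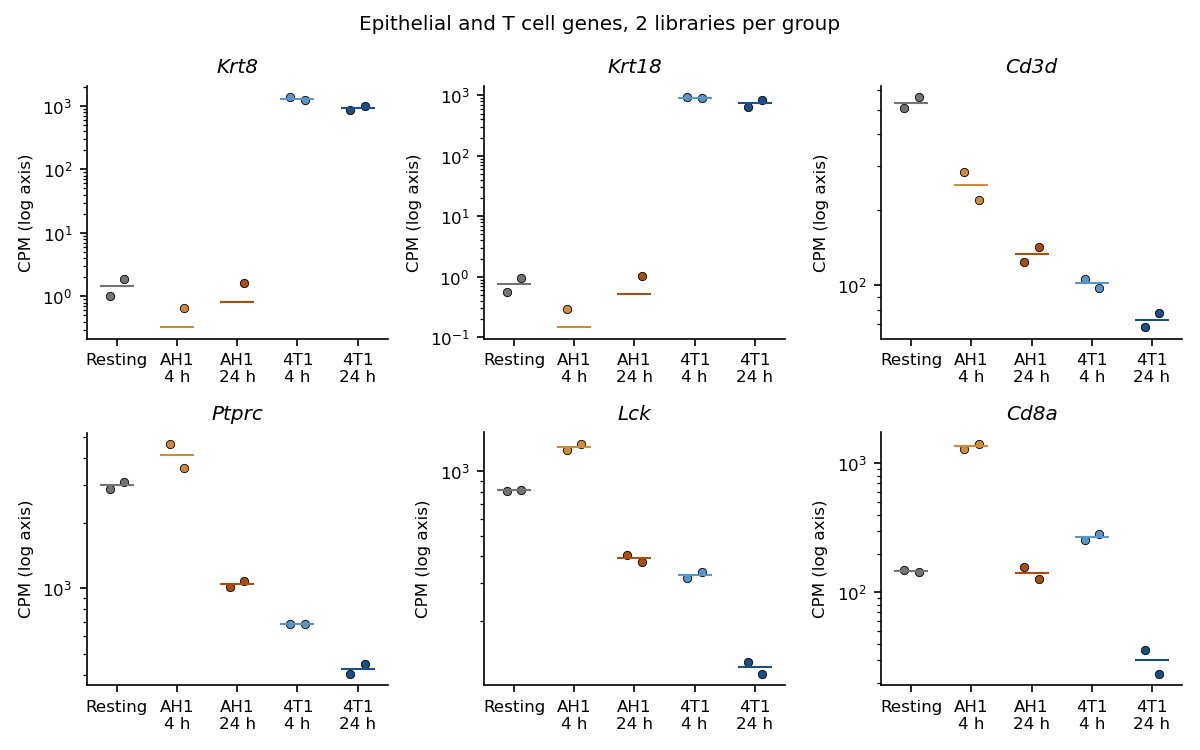
CPM on a log axis of 2 keratins and of T cell genes (Cd3d, Ptprc, Lck and Cd8a) in each library, with points for libraries. Krt8 averaged 1306 and 931 CPM in co-culture at 4 h and 24 h and 1.43 CPM at rest.

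With peptide for 4 h, CTLs made far more cytokine transcripts than at rest, in the comparison that set antigen without tumor cells against rest. Ifng, the macrophage-activating cytokine of CTLs, rose from 199 ± 13.9 to 113698 ± 21123 CPM, and Tnf, an inflammatory cytokine, from 204 ± 0.950 to 5020 ± 1011 CPM (SD, n = 2). The chemokines Ccl3 and Ccl4 rose by log2 fold changes of 11.34 ± 0.23 and 7.85 ± 0.19. Ccl1, a chemokine without a count at rest, was at least 57208-fold higher, and the growth factor Il3 at least 296-fold higher. Of 22 tested cytokine and chemokine genes, 18 rose and 3 fell (18 up and 3 down adjusted over the list alone). Those that fell included Csf1, a macrophage growth factor (-3.47 ± 0.21, adjusted p = 2.3e-08), and Ltb, a membrane lymphotoxin chain (-1.76 ± 0.13, adjusted p = 1.5e-07). The list stood apart from other genes (camera adjusted p = 3.7e-07, and adjusted p = 0.0311 with an estimated correlation). Such folds against a group at 0 use a floor of 3 counts over the group, and they, like all counting intervals here, cover counting error only.

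Slc7a5 rose by a log2 fold change of 4.27 ± 0.29, adjusted p = 5.1e-08, and Slc3a2 by 2.07 ± 0.17, adjusted p = 3.8e-07. The list of 21 amino acid transporter genes, which holds both, had 12 risen and 4 fallen (12 up and 4 down adjusted over the list alone; camera adjusted p = 0.0167, and adjusted p = 0.368 with an estimated correlation). The glutamine carrier Slc1a5 rose by 3.22 ± 0.16 and the cationic amino acid carrier Slc7a1 by 2.94 ± 0.20, whereas the lysosomal exporter Slc36a1 changed by -3.18 ± 0.24 and the branched-chain amino acid carrier Slc43a2 by -3.35 ± 0.29. Among 19 cytosolic aminoacyl-tRNA synthetases, which load amino acids onto tRNA, 17 rose and 0 fell (17 up and 0 down adjusted over the list alone), including Tars (2.82 ± 0.14) and Iars (3.07 ± 0.17). That list gave camera adjusted p = 6.2e-07, and adjusted p = 0.102 with an estimated correlation. The tryptophan and aryl hydrocarbon receptor genes went both ways, with 6 higher and 7 lower of 19 (6 up and 7 down adjusted over the list alone; camera adjusted p = 0.633). Wars, the tryptophanyl-tRNA synthetase, rose by 1.97 ± 0.19, adjusted p = 1.1e-06. Qprt of NAD synthesis changed by -3.48 ± 0.40, adjusted p = 6.9e-06, and Ido1, which degrades tryptophan, by -3.31 ± 0.44, adjusted p = 2.2e-05.

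Genes for making ribosomes rose as a group: 35 of 35 were higher (35 up and 0 down adjusted over the list alone; camera adjusted p = 8.1e-17, and adjusted p = 0.0311 with an estimated correlation). Examples were the nucleolar genes Nop2 (4.90 ± 0.20) and Rrp9 (4.26 ± 0.15) and the growth regulator Myc (2.86 ± 0.17). Of 15 serine and one-carbon genes, 12 rose and 3 fell (12 up and 3 down adjusted over the list alone; camera adjusted p = 6.3e-04, and adjusted p = 0.102 with an estimated correlation). Integrated stress response genes downstream of Atf4 had 14 risen and 3 fallen of 20 (14 up and 3 down adjusted over the list alone; camera adjusted p = 7.6e-04, and adjusted p = 0.102 with an estimated correlation). Heat shock chaperones had 15 risen and 1 fallen of 19 (15 up and 1 down adjusted over the list alone; camera adjusted p = 6.2e-05, and adjusted p = 0.102 with an estimated correlation). The proliferation marker Mki67 was lower (-2.22 ± 0.15, adjusted p = 5.2e-08).

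Killing genes went both ways. Gzmb, the protease of cytotoxic granules, rose from 287 ± 16.8 to 3522 ± 100.2 CPM and Prf1, the pore-forming protein, from 236 ± 1.27 to 571 ± 42.4 CPM, while the receptor chain Klrd1 fell by 3.99 on the log2 scale (adjusted p = 1.1e-09). Among 17 activation and costimulatory receptors, 10 rose and 4 fell (11 up and 4 down adjusted over the list alone; camera adjusted p = 0.0325, and adjusted p = 0.286 with an estimated correlation). The interleukin-2 receptor chain Il2ra changed by 4.39 ± 0.17 and the costimulator Tnfrsf9 by 4.95 ± 0.18. Inhibitory receptor and exhaustion genes had 12 risen and 2 fallen of 18 (12 up and 2 down adjusted over the list alone; camera adjusted p = 0.00187, and adjusted p = 0.102 with an estimated correlation). Pdcd1, which encodes PD-1, rose by 4.81 ± 0.15 and Havcr2, which encodes TIM-3, by 4.94 ± 0.18, but Ctla4, another inhibitory receptor, changed by -4.91 ± 0.20, adjusted p = 1.1e-09. Early T cell receptor response genes had 18 risen and 7 fallen of 31 (18 up and 7 down adjusted over the list alone; camera adjusted p = 0.00782, and adjusted p = 0.575 with an estimated correlation). Type I interferon response genes had 16 risen and 2 fallen of 24 (17 up and 2 down adjusted over the list alone; camera adjusted p = 0.00187, and adjusted p = 0.308 with an estimated correlation). Those that rose included the RNA sensor Ifih1 (4.22 ± 0.16) and the antiviral enzyme Rsad2 (5.70 ± 0.30).

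Markers of B cells and some of myeloid cells were also higher with peptide. All 13 tested B cell markers rose (13 up and 0 down adjusted over the list alone; camera adjusted p = 3.7e-07, and adjusted p = 0.286 with an estimated correlation), with a median log2 fold change of 7.89, or 6.90 with the 6 genes absent at rest held at their bound. Cd79b, a signaling chain of the B cell receptor, was at least 432-fold higher, and Igkc, the kappa light chain, reached 137 ± 17.6 CPM (SD, n = 2). Of 14 myeloid markers, 9 rose and 0 fell (9 up and 0 down adjusted over the list alone; camera adjusted p = 0.00187, and adjusted p = 0.409 with an estimated correlation), among them S100a8 (at least 127-fold) and Mpeg1 (4.77 ± 0.23). Epithelial and stromal markers had 6 and 4 genes risen against 4 and 2 fallen (6 up and 4 down, and 4 up and 2 down, adjusted over the list alone, camera adjusted p = 0.924 and 0.633). In all, 4244 genes rose and 4518 fell, and the lowest included Slc5a9 and Art2b, at least 89.7-fold and 62.8-fold lower. Library totals alone moved the median of all genes to -0.54, put 31.0% of calls higher in place of 48.4%, and gave Prf1 0.77. T cell identity scaling moved that median to -0.33 and the higher share to 38.0%.

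After 24 h with peptide the cells carried a proliferation program, in the comparison that asked what antigen left in place after a day. All 38 cell cycle genes rose (38 up and 0 down adjusted over the list alone; camera adjusted p = 1.2e-18, and adjusted p = 0.0422 with an estimated correlation), including Ccna2, a cyclin of S and G2 phase (5.86 ± 0.21), and Mcm5 of the replicative helicase (4.22 ± 0.14). Mki67 went from 78.2 ± 3.38 to 461 ± 3.54 CPM (SD, n = 2). Gzmb reached 5576 ± 263 CPM against 287 ± 16.8 at rest, and Ifng remained above rest (2.37 ± 0.18, adjusted p = 2.4e-07). Prf1 did not pass the test (0.17 ± 0.15, adjusted p = 0.348) but did with T cell identity scaling (1.26, adjusted p = 9.2e-06). Tnf changed by -0.75 ± 0.17, adjusted p = 0.00238, a sign that turned to 0.34 with that scaling (adjusted p = 0.0873). The 17 T cell identity genes had a median of -0.55 by the main scaling, so both shifts may reflect these reference genes.

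Slc7a5 was higher by a log2 fold change of 3.85 ± 0.28, adjusted p = 1.4e-07, and Slc3a2 by 0.73 ± 0.17, adjusted p = 0.00254. Biosynthesis genes rose with them. Ribosome biogenesis genes had 35 risen of 35 (35 up and 0 down adjusted over the list alone; camera adjusted p = 1.7e-14, and adjusted p = 0.0422 with an estimated correlation). Serine and one-carbon genes had 14 risen and 1 fallen of 15 (14 up and 1 down adjusted over the list alone; camera adjusted p = 3.0e-08, and adjusted p = 0.0422 with an estimated correlation). Phgdh and Psat1, the opening enzymes of serine synthesis, rose by 3.53 ± 0.13 and 4.42 ± 0.16. Of 19 aminoacyl-tRNA synthetases 17 rose and 0 fell (17 up and 0 down adjusted over the list alone; camera adjusted p = 1.7e-07, and adjusted p = 0.0896 with an estimated correlation), such as Farsb (2.39 ± 0.16). Oxidative phosphorylation genes had 28 risen and 1 fallen of 36 (28 up and 2 down adjusted over the list alone; camera adjusted p = 4.2e-05, and adjusted p = 0.283 with an estimated correlation). Cholesterol synthesis genes had 19 risen and 1 fallen of 23 (19 up and 1 down adjusted over the list alone; camera adjusted p = 4.8e-05, and adjusted p = 0.0896 with an estimated correlation).

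Other groups fell. Of 31 early T cell receptor response genes, 22 fell and 6 rose (6 up and 22 down adjusted over the list alone; camera adjusted p = 1.4e-05, and adjusted p = 0.359 with an estimated correlation), and 16 fell and 8 rose with T cell identity scaling. Those that fell included the AP-1 genes Fos (-6.75 ± 0.26) and Fosb (-7.93 ± 0.37) and the early surface marker Cd69 (-5.62 ± 0.31). Type I interferon response genes had 16 fallen and 3 risen of 24 (3 up and 17 down adjusted over the list alone; camera adjusted p = 9.6e-04, and adjusted p = 0.252 with an estimated correlation), a median of -1.07 that turned to 0.02 with T cell identity scaling. Isg20 and Rtp4 changed by -3.78 ± 0.22 and -3.13 ± 0.19 while Oasl1 rose by 4.53 ± 0.43. TGF-beta response and residency genes had 14 fallen and 2 risen of 18 (2 up and 15 down adjusted over the list alone; camera adjusted p = 1.4e-04, and adjusted p = 0.244 with an estimated correlation), and 9 fallen and 3 risen with that scaling. Ctla4 changed by -7.15 ± 0.22 and the interleukin-7 receptor Il7r by -3.27 ± 0.15, whereas Tnfrsf8, which encodes CD30, and Il2ra rose by 5.41 ± 0.19 and 3.54 ± 0.17. Among 17 T cell identity genes 11 fell and 1 rose (1 up and 12 down adjusted over the list alone; camera adjusted p = 0.00329, and adjusted p = 0.244 with an estimated correlation). Cd3d changed by -2.01 ± 0.16, Cd3g by -1.93 ± 0.16 and Ptprc, which encodes CD45, by -1.51 ± 0.14. Scaled on those genes themselves, 9 rose and 5 fell.

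B cell markers again rose in all 13 of 13 cases (13 up and 0 down adjusted over the list alone; camera adjusted p = 1.2e-07, and adjusted p = 0.244 with an estimated correlation), with Cd79b and Ms4a1 at least 326-fold and 252-fold higher and a median of 7.54, or 6.67 at the bounds. In all, 4299 genes rose and 3840 fell, the latter including Dmrta1, at least 175-fold lower. Under T cell identity scaling the median of all genes stood at 1.10 and 87.6% of calls were higher in place of 52.8%.

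Co-culture for 4 h asked what contact with tumor cells did to the resting line, and epithelial genes were among its largest differences. Krt18, a partner of Krt8, rose by a log2 fold change of 10.24 ± 0.50 and the epithelial adhesion gene Epcam by 9.46 ± 0.33. The receptor kinase gene Epha2 and the sphingomyelin synthase Sgms2, without a count at rest, were at least 2495-fold and 1318-fold higher. Of 25 epithelial markers 24 rose and 0 fell (24 up and 0 down adjusted over the list alone; camera adjusted p = 1.7e-09, and adjusted p = 0.189 with an estimated correlation), with a median of 9.86, or 9.04 at the bounds of 5 genes. Stromal markers had 16 risen and 1 fallen of 22 (16 up and 1 down adjusted over the list alone; camera adjusted p = 8.4e-04, and adjusted p = 0.481 with an estimated correlation), including the matrix genes Thbs1 (9.29 ± 0.30) and Lamb1 (9.75 ± 0.36).

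T cell genes were lower in the same libraries. Of 17 T cell identity genes 14 fell and 1 rose (1 up and 14 down adjusted over the list alone; camera adjusted p = 5.7e-05, and adjusted p = 0.189 with an estimated correlation). Cd3d changed by -2.39 ± 0.16 and Ptprc by -2.12 ± 0.14, although Cd8a rose by 0.88 ± 0.18, adjusted p = 8.1e-04. Scaled on that list, 5 rose and 6 fell. Slc7a5 rose by 2.78 ± 0.27, adjusted p = 1.4e-06, and Slc3a2 by 0.68 ± 0.17, adjusted p = 0.00347, and these became 4.12 and 2.03 with T cell identity scaling. Whether these transcripts came from CTLs or 4T1 cells was not tested, and that scaling raises transcripts of 4T1 cells too.

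Several activation genes rose even so. Xcl1, a chemokine of CD8 T cells, rose by 5.04 ± 0.29 and Ccl3 by 3.12 ± 0.17, and Ccl1 was at least 263-fold higher. Lif, a cytokine of the interleukin-6 family, rose by 9.76 ± 0.30, but its pattern differed. It had only 55 and 78 counts with peptide at 4 h, and still 5118 and 3616 in co-culture at 24 h. Whether Lif came from 4T1 cells was not tested. Il2ra rose by 1.74 ± 0.16, Tnfrsf9 by 2.32 ± 0.16, Pdcd1 by 2.09 ± 0.14, Havcr2 by 2.16 ± 0.16 and the early response factor Nr4a1 by 1.55 ± 0.18. Their lists did not rise alike, and by the main scaling the 17 activation and costimulatory receptors had a median of -1.71. The medians were -0.16 for 18 inhibitory receptor genes and 0.14 for 31 early T cell receptor response genes. Ifng did not pass the test (0.04 ± 0.18, adjusted p = 0.859), and its sign turned to -0.02 with a minimum of 1 CPM and to -0.05 without resting replicate 1. With T cell identity scaling it passed (1.39, adjusted p = 1.8e-05). Fosb and Cd69 changed by -5.43 ± 0.31 and -4.49 ± 0.28.

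Cytotoxic effector genes had 10 fallen and 1 risen of 18 (1 up and 10 down adjusted over the list alone; camera adjusted p = 0.00854, and adjusted p = 0.303 with an estimated correlation), but 10 risen and 2 fallen with T cell identity scaling. Gzmb changed by -0.37 ± 0.12, adjusted p = 0.0178, and Prf1 did not pass the test (-0.21 ± 0.15, adjusted p = 0.235), and both turned upward with that scaling, to 0.98 (adjusted p = 1.7e-05) and 1.14 (adjusted p = 1.6e-05). Klrd1 was lower under both scalings (-2.76 ± 0.15, then -1.41, adjusted p = 4.3e-06). The call on Gzmb ended without resting replicate 2 (adjusted p = 0.133) or either co-culture 4 h library (adjusted p = 0.0929 and 0.0918) and with library totals (0.0503), and Prf1 passed when only the groups compared were fitted (0.0311). Memory and quiescence genes had 15 fallen and 5 risen of 23 (5 up and 15 down adjusted over the list alone; camera adjusted p = 0.0225, and adjusted p = 0.401 with an estimated correlation), but 8 risen and 7 fallen with T cell identity scaling. Their median was -1.25 but their mean 0.23, and the list test pointed down.

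Growth genes were higher beside the epithelial markers. Cell cycle genes had 33 risen and 2 fallen of 38 (33 up and 2 down adjusted over the list alone; camera adjusted p = 6.8e-09, and adjusted p = 0.129 with an estimated correlation), led by the mitotic enzyme Ube2c (5.63 ± 0.20). Ribosome biogenesis genes had 34 of 35 risen (34 up and 0 down adjusted over the list alone; camera adjusted p = 1.7e-09, and adjusted p = 0.129 with an estimated correlation). Serine and one-carbon genes had 13 of 15 risen (13 up and 0 down adjusted over the list alone; camera adjusted p = 4.8e-05, and adjusted p = 0.129 with an estimated correlation). Ahr, the aryl hydrocarbon receptor that binds tryptophan metabolites, rose by 5.82 ± 0.52, adjusted p = 5.4e-07, and Wars by 3.27 ± 0.19, adjusted p = 1.4e-08. In all, 5033 genes rose and 3932 fell. The median of all genes moved to 1.40 with T cell identity scaling, which made 91.6% of calls higher in place of 56.1%, and to 0.15 with library totals alone.

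By 24 h of co-culture, interferon response genes stood far above rest. The CXCR3 ligands Cxcl9 and Cxcl10 rose by log2 fold changes of 11.48 ± 0.49 and 8.87 ± 0.25, the ubiquitin-like Isg15 by 4.17 ± 0.19, the tetherin gene Bst2 by 2.54 ± 0.13 and Rsad2 by 5.95 ± 0.30. Of 24 type I interferon response genes 23 rose and 1 fell (23 up and 1 down adjusted over the list alone; camera adjusted p = 8.7e-07, and adjusted p = 0.103 with an estimated correlation). The exception was Mx1, an antiviral GTPase (-1.58 ± 0.14, adjusted p = 5.7e-07, or 1.01 with T cell identity scaling, adjusted p = 3.5e-05). Interferon-gamma response genes had 17 risen and 8 fallen of 28 (17 up and 8 down adjusted over the list alone; camera adjusted p = 0.0184, and adjusted p = 0.163 with an estimated correlation). Ido1, an interferon-induced enzyme that degrades tryptophan, rose by 2.54 ± 0.33, adjusted p = 1.5e-05, Ahr by 5.87 ± 0.52, adjusted p = 4.1e-07, and Wars by 2.58 ± 0.19, adjusted p = 7.4e-08.

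Slc7a5 was above rest by 2.56 ± 0.27, adjusted p = 2.4e-06. Slc3a2 did not pass the test (0.23 ± 0.17, adjusted p = 0.254), although it did without co-culture 24 h replicate 2 (0.45, adjusted p = 0.043). With T cell identity scaling the values were 5.15 and 2.82, and Slc3a2 passed (adjusted p = 6.0e-09). The cells these transcripts came from were not tested here either.

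Effector transcripts were below rest by the main scaling. Ifng stood at 16.4 ± 4.72 CPM against 199 ± 13.9, Tnf at 21 ± 3.6 against 204 ± 0.950, Gzmb at 77.9 ± 6.21 against 287 ± 16.8 and Prf1 at 31.5 ± 6.11 against 236 ± 1.27 CPM (SD, n = 2). T cell identity scaling gave log2 fold changes of -1.01 for Ifng, -0.69 for Tnf, -0.31 for Prf1 and, in the other direction, 0.71 for Gzmb. With it the call on Prf1 ended (adjusted p = 0.0754), and Gzmb passed upward (adjusted p = 2.2e-04). Cytotoxic effector genes had 15 fallen and 2 risen of 18 (2 up and 15 down adjusted over the list alone; camera adjusted p = 4.7e-05, and adjusted p = 0.103 with an estimated correlation), against 9 risen and 1 fallen with that scaling. The same turn held for cytokines and chemokines, with 12 fallen and 4 risen of 22 (4 up and 12 down adjusted over the list alone; camera adjusted p = 0.00919, and adjusted p = 0.103 with an estimated correlation) but 11 risen and 4 fallen. It also held for the activation receptors, with 15 fallen and 2 risen of 17 (2 up and 15 down adjusted over the list alone; camera adjusted p = 4.7e-05, and adjusted p = 0.097 with an estimated correlation) but 8 risen and 2 fallen. Il2ra changed by -2.17 ± 0.16 and Tnfrsf9 by -1.94 ± 0.17, which turned to 0.42 (adjusted p = 0.0197) and 0.65 (adjusted p = 0.00291). Early T cell receptor response genes had 22 fallen and 6 risen of 31 (6 up and 22 down adjusted over the list alone; camera adjusted p = 3.0e-04, and adjusted p = 0.417 with an estimated correlation) but 19 risen and 9 fallen after that scaling. Fosb and Cd69 stayed lower under both (-6.80 and -6.15, then -4.22 and -3.56). T cell identity scaling moved the median of all genes to 2.63 here, so an upward turn is not particular to these lists.

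Epithelial markers were again among the highest genes. Of 25, 24 rose and 0 fell (24 up and 0 down adjusted over the list alone; camera adjusted p = 1.4e-08, and adjusted p = 0.103 with an estimated correlation), with a median of 9.54, or 9.25 at the bounds. Epcam rose by 9.25 ± 0.33 and Krt8 by 9.37 ± 0.57, and Epha2 and the epithelial cytokine Tslp were at least 1813-fold and 1198-fold higher. Stromal markers had 14 risen and 1 fallen of 22 (14 up and 1 down adjusted over the list alone; camera adjusted p = 0.00414, and adjusted p = 0.45 with an estimated correlation). T cell identity genes had 16 fallen of 17 (0 up and 16 down adjusted over the list alone; camera adjusted p = 5.7e-08, and adjusted p = 0.097 with an estimated correlation), and 1 fallen and 1 risen scaled on themselves. The kinase Lck changed by -2.74 ± 0.13, Ptprc by -2.81 ± 0.15 and Cd8b1 by -2.69 ± 0.14. Scaled on the list, their calls ended (-0.15, -0.22 and -0.10, adjusted p = 0.299, 0.209 and 0.553). Cell cycle genes had 36 risen and 2 fallen of 38 (36 up and 2 down adjusted over the list alone; camera adjusted p = 3.5e-11, and adjusted p = 0.097 with an estimated correlation). Mki67 changed by 2.36 ± 0.14. In all, 5306 genes rose and 4311 fell, among them Chrna2, at least 74.7-fold lower. T cell identity scaling moved the median of all genes to 2.63 and the higher share of calls from 55.2% to 98.0%, and library totals alone moved the median to 0.11.

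**Figure D3:**
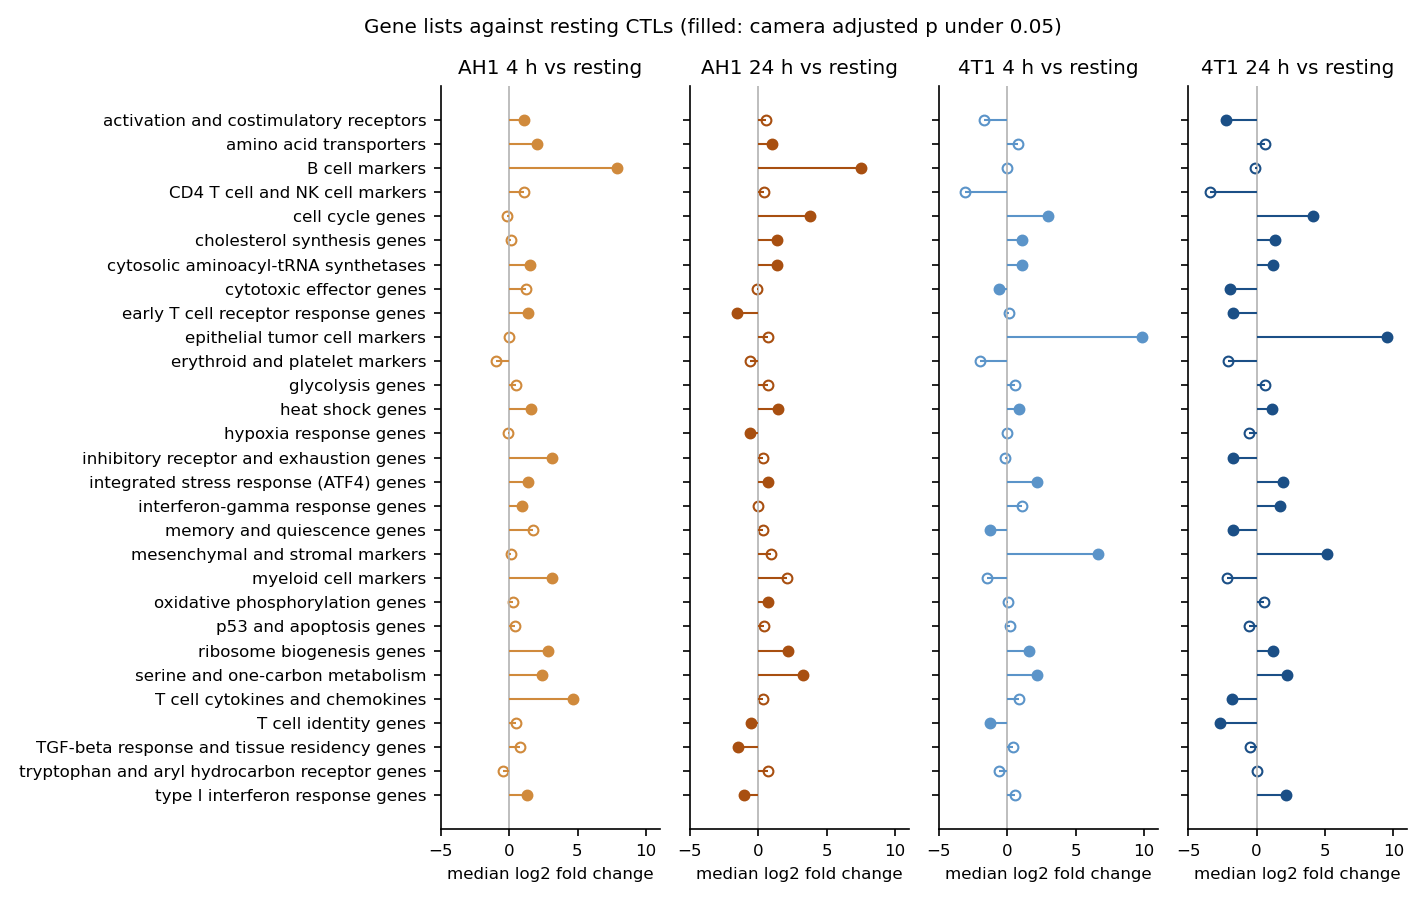
Median log2 fold change of the 29 gene lists in the 4 comparisons with rest, where filled points mark a camera adjusted p under 0.05. In 24 h co-culture the type I interferon list had a median of 2.16 and the cytotoxic list of -1.97, the latter turning to 0.62 with T cell identity scaling.

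Co-culture against peptide at 4 h set tumor contact beside free antigen at the same time. The cytokine response was far lower in co-culture. Ifng stood at 204 ± 9.01 CPM against 113698 ± 21123 with peptide, and Tnf at 117 ± 12.3 against 5020 ± 1011 CPM (SD, n = 2). Ccl3 and Ccl4 differed by -8.22 ± 0.20 and -6.93 ± 0.18, while Lif was higher in co-culture (6.39 ± 0.24). Of 22 cytokine and chemokine genes 18 were lower and 2 higher (2 up and 18 down adjusted over the list alone; camera adjusted p = 1.8e-08, and adjusted p = 0.0367 with an estimated correlation), and with T cell identity scaling still 16 were lower and 4 higher.

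Slc7a5 was lower by the main scaling (-1.495 ± 0.25, adjusted p = 1.8e-04) and so was Slc3a2 (-1.38 ± 0.17, adjusted p = 1.2e-05), but both turned to the other side of 0 with T cell identity scaling, at 0.15 (adjusted p = 0.584) and 0.26 (adjusted p = 0.174). Activation receptors had 14 lower and 1 higher of 17 (1 up and 14 down adjusted over the list alone; camera adjusted p = 1.1e-05, and adjusted p = 0.0564 with an estimated correlation), and 9 lower and 7 higher with that scaling. Il2ra differed by -2.66 ± 0.16 and Tnfrsf9 by -2.63 ± 0.16. Inhibitory receptor genes had 13 lower and 1 higher of 18 (1 up and 14 down adjusted over the list alone; camera adjusted p = 6.5e-05, and adjusted p = 0.0564 with an estimated correlation), and 8 lower and 3 higher with T cell identity scaling. Pdcd1 changed by -2.72 ± 0.14 and Havcr2 by -2.78 ± 0.17. Gzmb was lower (-3.99 ± 0.14, or -2.35 with T cell identity scaling), and so was Prf1 (-1.48 ± 0.15), which turned to 0.16 (adjusted p = 0.337). Cytotoxic effector genes had 13 lower and 4 higher of 18 (4 up and 13 down adjusted over the list alone; camera adjusted p = 0.00541, and adjusted p = 0.266 with an estimated correlation), but 8 higher and 4 lower with that scaling.

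**Figure D4:**
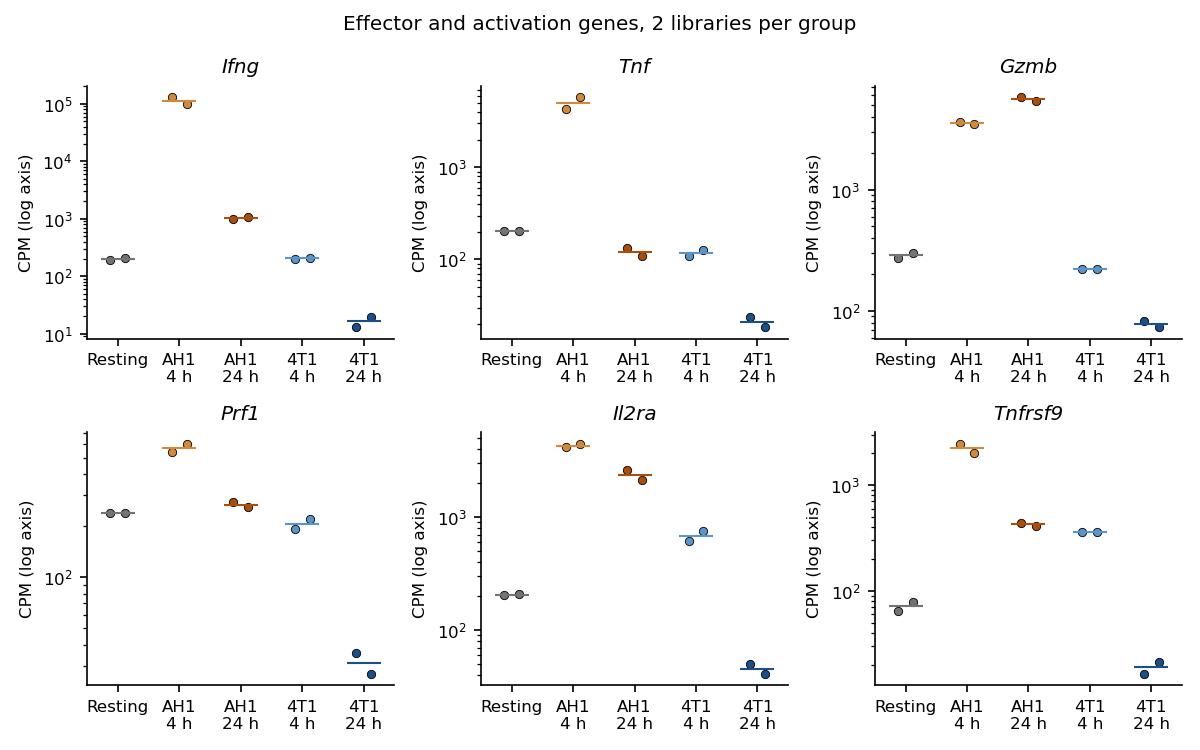
CPM on a log axis of Ifng, Tnf, Gzmb, Prf1, Il2ra and Tnfrsf9 in each library, with points for libraries and bars for group means. Ifng averaged 199 CPM at rest and 204 CPM in 4 h co-culture, against 113698 CPM with peptide at 4 h.

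Ribosome biogenesis genes had 34 of 35 lower (0 up and 35 down adjusted over the list alone; camera adjusted p = 7.8e-10, and adjusted p = 0.0564 with an estimated correlation), such as Myc (-2.72 ± 0.17) and the rRNA methyltransferase Fbl (-1.95 ± 0.13), but 22 higher and 3 lower with T cell identity scaling, where the call on Fbl ended (-0.31, adjusted p = 0.0576). Cell cycle genes went the other way, with 35 higher and 2 lower of 38 (35 up and 2 down adjusted over the list alone; camera adjusted p = 7.5e-09, and adjusted p = 0.0564 with an estimated correlation), including Top2a, a topoisomerase of dividing cells (4.69 ± 0.17), and with Mki67 at 3.15 ± 0.15. Ahr was higher by 3.55 ± 0.43, adjusted p = 9.6e-06, and Ido1 by 2.47 ± 0.45, adjusted p = 3.4e-04, the latter by 3.80 without peptide 4 h replicate 2.

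Marker genes also separated the groups. Epithelial markers had 24 higher and 0 lower of 25 (24 up and 0 down adjusted over the list alone; camera adjusted p = 7.7e-09, and adjusted p = 0.188 with an estimated correlation), with a median of 10.16, or 7.45 at the bounds of 10 genes. The keratin Krt7, the tight junction gene Cldn4 and the granulocyte growth factor Csf3 were at least 5297-fold, 4258-fold and 5247-fold higher, and Epcam was higher by 7.45 ± 0.28. B cell markers had 13 of 13 lower (0 up and 13 down adjusted over the list alone; camera adjusted p = 7.7e-09, and adjusted p = 0.228 with an estimated correlation), a median of -9.38, or -7.39 at the bounds, with Ms4a1 at least 314-fold lower. Myeloid markers had 12 of 14 lower (0 up and 12 down adjusted over the list alone; camera adjusted p = 6.5e-05, and adjusted p = 0.266 with an estimated correlation), with S100a9 at least 307-fold lower. T cell identity genes had 16 lower and 1 higher of 17 (1 up and 16 down adjusted over the list alone; camera adjusted p = 1.3e-07, and adjusted p = 0.0685 with an estimated correlation), including Lck (-1.98 ± 0.13), Ptprc (-2.59 ± 0.15) and Thy1 (-2.49 ± 0.16). Scaled on themselves, 9 were lower and 3 higher. In all, 5170 genes were higher and 3870 lower, a higher share of 57.2% that became 79.6% with library totals alone and 94.9% with T cell identity scaling. The median of all genes was 0.16 by the main scaling, 0.75 by library totals and 1.79 by T cell identity scaling, and with library totals Slc7a5, Slc3a2 and Prf1 had log2 fold changes of -0.91, -0.79 and -0.89.

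At 24 h, the same comparison of co-culture with peptide set interferon genes against activation genes. Rtp4, Oas1a and the GTPase Gbp4 were higher in co-culture by log2 fold changes of 5.16 ± 0.19, 5.12 ± 0.24 and 3.72 ± 0.13, and the transcription factor Irf1 by 3.002 ± 0.13. All 24 type I interferon response genes were higher (24 up and 0 down adjusted over the list alone; camera adjusted p = 3.5e-12, and adjusted p = 0.0737 with an estimated correlation). Interferon-gamma response genes had 20 higher and 3 lower of 28 (20 up and 3 down adjusted over the list alone; camera adjusted p = 1.4e-05, and adjusted p = 0.0737 with an estimated correlation). Ido1 was higher by 6.29 ± 0.43, adjusted p = 5.4e-08, and Ahr by 5.14 ± 0.47, adjusted p = 9.7e-07.

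Gzmb averaged 77.9 ± 6.21 CPM in co-culture and 5576 ± 263 CPM with peptide (SD, n = 2). It stayed lower with T cell identity scaling (-6.16, then -4.66), as did Prf1 (-3.07, then -1.57), Ifng (-5.97, then -4.48), the lymphotoxin Lta (-6.34, then -4.83) and Tnf (-2.53, then -1.03). Activation receptors had 14 lower and 1 higher of 17 (1 up and 14 down adjusted over the list alone; camera adjusted p = 2.5e-06, and adjusted p = 0.0737 with an estimated correlation), and 9 lower and 5 higher with that scaling. Tnfrsf8 differed by -8.32 ± 0.23, Il2ra by -5.70 ± 0.19, Tnfrsf9 by -4.50 ± 0.18 and Irf4, a factor induced by T cell receptor signals, by -4.46 ± 0.24, while Ctla4 and Il7r were higher (2.74 ± 0.19 and 0.60 ± 0.14). By the main scaling both were still below rest in co-culture at 24 h. Ctla4 averaged 42.4 CPM there against 906 CPM at rest, and Il7r 130 against 822 CPM. Cytotoxic effector genes had 12 lower and 5 higher of 18 (5 up and 12 down adjusted over the list alone; camera adjusted p = 0.00518, and adjusted p = 0.281 with an estimated correlation), but 7 higher and 6 lower with T cell identity scaling.

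Slc7a5 was lower (-1.30 ± 0.25, adjusted p = 7.1e-04), but it turned to 0.21 (adjusted p = 0.431) with T cell identity scaling. Slc3a2 was lower as well (-0.51 ± 0.17, adjusted p = 0.0228), turning to 1.00 (adjusted p = 1.4e-04), and its call ended without peptide 24 h replicate 1 (-0.38, adjusted p = 0.152) or co-culture 24 h replicate 2 (-0.29, adjusted p = 0.208). Ribosome biogenesis genes had 29 of 35 lower (0 up and 29 down adjusted over the list alone; camera adjusted p = 6.7e-08, and adjusted p = 0.0737 with an estimated correlation) but 29 higher with T cell identity scaling. Serine and one-carbon genes had 11 of 15 lower (0 up and 12 down adjusted over the list alone; camera adjusted p = 5.5e-04, and adjusted p = 0.123 with an estimated correlation) but 11 higher with that scaling. Myc was lower (-1.79), but its call ended with T cell identity scaling (-0.28, adjusted p = 0.13). Mki67 did not pass the test (-0.20 ± 0.13, adjusted p = 0.228) but passed upward with that scaling (1.30, adjusted p = 3.0e-06).

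Epithelial markers had 23 higher and 1 lower of 25 (23 up and 1 down adjusted over the list alone; camera adjusted p = 4.0e-10, and adjusted p = 0.141 with an estimated correlation), a median of 8.87, or 8.40 at the bounds. Cldn4 and Wfdc2 were at least 4931-fold and 4032-fold higher, and Epcam was higher by 9.92 ± 0.34. B cell markers had 13 of 13 lower (0 up and 13 down adjusted over the list alone; camera adjusted p = 2.7e-09, and adjusted p = 0.191 with an estimated correlation), a median of -9.84, or -7.28 at the bounds, with Cd79b at least 412-fold lower. All 17 T cell identity genes were lower (0 up and 17 down adjusted over the list alone; camera adjusted p = 1.2e-08, and adjusted p = 0.0737 with an estimated correlation). Thy1 changed by -2.60 ± 0.16 and Lck by -1.69 ± 0.13, and scaled on themselves 2 were higher and 7 lower, with no call on Lck (-0.19, adjusted p = 0.2). In all, 4214 genes were higher and 3528 lower. With T cell identity scaling the median of all genes was 1.52, and 93.7% of calls were higher in place of 54.4%.

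From 4 h to 24 h with peptide, the early response subsided and the cell cycle genes rose. Ccl1, Ccl3 and the early response factor Nr4a3 changed by log2 fold changes of -13.97 ± 0.38, -11.16 ± 0.23 and -7.87 ± 0.20, Ifng by -6.79 ± 0.23, Tnf by -5.37 ± 0.20 and Nr4a1 by -4.10 ± 0.19, and Il3 was at least 339-fold lower. Of 22 cytokine and chemokine genes 18 fell and 0 rose (0 up and 18 down adjusted over the list alone; camera adjusted p = 3.9e-11, and adjusted p = 0.0183 with an estimated correlation). Early T cell receptor response genes had 30 of 31 fallen (0 up and 30 down adjusted over the list alone; camera adjusted p = 6.8e-16, and adjusted p = 0.129 with an estimated correlation), and 23 with T cell identity scaling. Type I interferon response genes had 22 of 24 fallen (0 up and 23 down adjusted over the list alone; camera adjusted p = 3.9e-11, and adjusted p = 0.0777 with an estimated correlation), and 15 fallen and 2 risen with that scaling. Ifih1 changed by -4.73 ± 0.17 and Rsad2 by -5.80 ± 0.30. Inhibitory receptor genes had 12 fallen and 1 risen of 18 (1 up and 13 down adjusted over the list alone; camera adjusted p = 3.3e-06, and adjusted p = 0.0298 with an estimated correlation), and 7 and 1 with that scaling. Those that fell included the PD-L1 gene Cd274 (-3.49 ± 0.14), Havcr2 (-3.84 ± 0.17) and Pdcd1 (-3.03 ± 0.14).

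Cell cycle genes had 36 risen and 1 fallen of 38 (36 up and 1 down adjusted over the list alone; camera adjusted p = 2.8e-17, and adjusted p = 0.0285 with an estimated correlation). The nucleotide reductase Rrm2 changed by 7.68 ± 0.25, Top2a by 5.25 ± 0.18 and Mki67 by 4.78 ± 0.16. Aunip, a centrosome gene, was at least 99.0-fold higher. Gzmb rose further (0.66 ± 0.12, adjusted p = 4.6e-04) while Prf1 changed by -1.10 ± 0.15, adjusted p = 3.4e-05, which turned to 0.28 with T cell identity scaling (adjusted p = 0.119). Slc7a5 did not pass the test (-0.42 ± 0.24, adjusted p = 0.166), and its sign turned with library totals (0.14) and with T cell identity scaling (0.96, adjusted p = 0.00352). It passed with no count filter (adjusted p = 0.0265) and in the fit without co-culture libraries (adjusted p = 0.031). Slc3a2 changed by -1.33 ± 0.17, adjusted p = 2.2e-05, which turned to 0.05 with T cell identity scaling (adjusted p = 0.828). The T cell identity genes had a median of -1.63 by the main scaling, so turns with their scaling may reflect these reference genes. Ribosome biogenesis genes had 24 fallen and 1 risen of 35 (1 up and 24 down adjusted over the list alone; camera adjusted p = 3.3e-06, and adjusted p = 0.0957 with an estimated correlation) but 21 risen and 2 fallen with that scaling.

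T cell identity genes had 13 fallen and 2 risen of 17 (2 up and 13 down adjusted over the list alone; camera adjusted p = 6.9e-05, and adjusted p = 0.129 with an estimated correlation). Cd8a changed by -3.26 ± 0.19, and scaled on these genes themselves 5 rose and 5 fell. Myeloid markers had 8 of 14 fallen (0 up and 8 down adjusted over the list alone; camera adjusted p = 0.00194, and adjusted p = 0.397 with an estimated correlation), and 3 fallen and 1 risen with that scaling. Skeletal muscle genes were among the highest, with Myh1, Tnni2 and Myl1 at least 589-fold, 186-fold and 69.8-fold higher, and Acta1 higher by a count ratio of 4585 (95% counting interval 823 to 181134). These came from peptide 24 h replicate 2, without which the 4 genes had log2 fold changes of 5.77, 3.11, 4.58 and 4.56 and adjusted p from 0.0671 to 0.344. In all, 4158 genes rose and 3629 fell, a higher share of 53.4% that became 77.5% with library totals and 93.8% with T cell identity scaling. Those scalings moved the median of all genes to 0.60 and 1.40, and library totals gave -0.77 for Slc3a2, 1.23 for Gzmb and -0.54 for Prf1.

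From 4 h to 24 h of co-culture, type I interferon response genes rose, while early activation genes fell by the main scaling. Among the highest folds, the class II genes H2-Eb1, H2-Ab1 and H2-Aa rose by log2 fold changes of 7.18 ± 0.36, 6.78 ± 0.42 and 6.53 ± 0.52. All 24 type I interferon response genes rose (24 up and 0 down adjusted over the list alone; camera adjusted p = 6.7e-22, and adjusted p = 0.0261 with an estimated correlation), among them Mx2 (3.76 ± 0.25), the nucleic acid sensor Zbp1 (2.36 ± 0.14), Isg15 (2.35 ± 0.17) and Bst2 (2.05 ± 0.13). Ido1 rose by 3.38 ± 0.34, adjusted p = 2.0e-05, and Ctla4 by 1.00 ± 0.18, adjusted p = 0.00174. Ctla4 nonetheless stayed below rest, at 21.2 and 42.4 CPM at 4 h and 24 h against 906 CPM. Of 22 cytokine and chemokine genes 15 fell and 1 rose (1 up and 15 down adjusted over the list alone; camera adjusted p = 2.0e-11, and adjusted p = 0.0172 with an estimated correlation), and 11 fell and 3 rose with T cell identity scaling. Ccl1 changed by -5.60 ± 0.34, Xcl1 by -5.41 ± 0.30, Ccl3 by -4.91 ± 0.19, the costimulatory ligand Tnfsf14 by -4.37 ± 0.17 and Ifng by -3.64 ± 0.20.

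Early T cell receptor response genes had 29 of 31 fallen (0 up and 30 down adjusted over the list alone; camera adjusted p = 5.0e-21, and adjusted p = 0.079 with an estimated correlation), led by Nr4a3 (-4.39 ± 0.18). With T cell identity scaling 9 fell and 6 rose. Il2ra and Tnfrsf9 changed by -3.91 ± 0.17 and -4.26 ± 0.18, Prf1 by -2.70 ± 0.16 and Gzmb by -1.51 ± 0.13, whose call ended with that scaling (-0.27, adjusted p = 0.0792). Cell cycle genes had 32 of 38 risen (34 up and 0 down adjusted over the list alone; camera adjusted p = 1.5e-16, and adjusted p = 0.0261 with an estimated correlation). Top2a changed by 1.66 ± 0.15 and Mki67 by 1.43 ± 0.14. Ribosome biogenesis genes had 18 of 35 fallen (1 up and 24 down adjusted over the list alone; camera adjusted p = 5.3e-07, and adjusted p = 0.0663 with an estimated correlation) but 29 risen with T cell identity scaling. Hypoxia response genes had 8 of 19 fallen (0 up and 9 down adjusted over the list alone; camera adjusted p = 1.4e-04, and adjusted p = 0.0576 with an estimated correlation) but 17 risen with that scaling.

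Slc7a5 did not pass the test (-0.22 ± 0.25, adjusted p = 0.609), but it turned to 1.02 with T cell identity scaling and passed (adjusted p = 0.00224). Without co-culture 24 h replicate 1 it fell by 0.73 (adjusted p = 0.0423) and without replicate 2 it stood at 0.15 (adjusted p = 0.798). Slc3a2 did not pass either (-0.46 ± 0.17, adjusted p = 0.0851), turning to 0.79 with T cell identity scaling (adjusted p = 0.00107). It also passed with no count filter (adjusted p = 0.026), with DESeq2 (0.0287) and without co-culture 24 h replicate 1 (0.019).

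T cell identity genes had 14 fallen and 1 risen of 17 (1 up and 14 down adjusted over the list alone; camera adjusted p = 5.1e-10, and adjusted p = 0.0555 with an estimated correlation), and 4 fallen and 4 risen scaled on themselves. The adaptor Lat changed by -1.93 ± 0.14 and Cd8b1 by -1.70 ± 0.14. Neither Krt8 (-0.49 ± 0.36, adjusted p = 0.413) nor Epcam (-0.21 ± 0.19, adjusted p = 0.526) passed the test, and both turned to the other side of 0 with T cell identity scaling (0.75 and 1.03, adjusted p = 0.102 and 5.0e-04). Krt8 passed with no count filter (adjusted p = 0.00806). In all, 1252 genes rose and 1181 fell. This total of 2433 dropped to 1189 or 848 without co-culture 4 h replicate 1 or 2, and to 1322 without co-culture 24 h replicate 2, and T cell identity scaling moved the median of all genes to 1.25 and the higher share from 51.5% to 98.3%.

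The difference between the time courses was tested as an interaction of source and time. A change with either source alone gives such a term too. Type I interferon response genes changed more in the upward direction in co-culture, all 24 of them (24 up and 0 down adjusted over the list alone; camera adjusted p = 1.3e-20, and adjusted p = 0.0257 with an estimated correlation). Interferon-gamma response genes had 21 with a higher and 1 with a lower change of 28 (21 up and 1 down adjusted over the list alone; camera adjusted p = 6.5e-09, and adjusted p = 0.0257 with an estimated correlation). From 4 h to 24 h this list had 21 fallen and 4 risen with peptide (4 up and 21 down adjusted over the list alone; camera adjusted p = 3.3e-05, and adjusted p = 0.0777 with an estimated correlation). In co-culture it had 15 risen and 3 fallen (17 up and 5 down adjusted over the list alone; camera adjusted p = 0.00724, and adjusted p = 0.147 with an estimated correlation). Cytokine genes had 14 with a higher and 2 with a lower change of 22 (14 up and 2 down adjusted over the list alone; camera adjusted p = 1.1e-07, and adjusted p = 0.0257 with an estimated correlation). Early T cell receptor response genes had 23 with a higher and 3 with a lower change of 31 (24 up and 3 down adjusted over the list alone; camera adjusted p = 9.4e-10, and adjusted p = 0.316 with an estimated correlation). Cytokine genes fell from 4 h to 24 h with both sources, and from a higher 4 h level with peptide. Early T cell receptor response genes fell with both by the main scaling, but in co-culture 9 fell and 6 rose with T cell identity scaling. Cell cycle genes had 35 with a lower and 1 with a higher change of 38 (1 up and 36 down adjusted over the list alone; camera adjusted p = 2.8e-16, and adjusted p = 0.0257 with an estimated correlation).

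Among named genes, Ccl1 (8.37 ± 0.79), Ifng (3.15 ± 0.26), Tnf (2.89 ± 0.25), Ido1 (3.82 ± 0.69), Ctla4 (3.24 ± 0.26) and S100a8 (8.96 ± 1.59) had a higher change in co-culture. S100a8 averaged 11.8 ± 4.75 and 0.0533 ± 0.0753 CPM with peptide and 0.121 ± 0.171 and 0.273 ± 0.123 CPM in co-culture (SD, n = 2), so its term came mostly from peptide. A lower change was seen for Gzmb (-2.17 ± 0.17), Prf1 (-1.59 ± 0.21), Il2ra (-3.05 ± 0.22), Tnfrsf9 (-1.87 ± 0.22), Mki67 (-3.35 ± 0.20), Aunip (-9.41 ± 1.45) and Tnni2 (-11.43 ± 3.42). Their adjusted p lay between 1.5e-07 for Mki67 and 0.0209 for Tnni2. Aunip, Ccl1, S100a8 and Tnni2 had groups at or near 0 counts, so the size of their terms depends on the prior count of the fit. Slc3a2 also differed (0.88 ± 0.24, adjusted p = 0.0116), whereas Slc7a5 did not pass (0.20 ± 0.35, adjusted p = 0.703) and turned to -0.38 with library totals and -0.31 without co-culture 24 h replicate 1. In all, 2331 genes had a higher and 2976 a lower change in co-culture, a higher share of 43.9% that became 16% with library totals and 35.5% with T cell identity scaling, as the median of all genes moved to -0.68 and -0.23.

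Calls ended for Slc3a2 with library totals (0.29, adjusted p = 0.4) and without co-culture 4 h replicate 1 (0.76, 0.0716), and for Ido1 without peptide 4 h replicate 2 (2.48, 0.0638). Tnni2 lost its call without peptide 4 h replicate 1 (0.0796) or 2 (0.0759) and without peptide 24 h replicate 2 (-2.99, 0.413).

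Peptide and co-culture were also compared by the genes that both changed against rest. At 4 h, 2396 genes rose and 2503 fell in both, while 1031 went in opposite directions. Independent lists of these sizes would share 1450 and 1206, and 20 simulations of unchanged groups against the same resting libraries shared 0. Unchanged groups give next to no calls, so that 0 does not gauge the excess. The fold changes had a correlation across genes of 0.371 (simulated 0.505) and a covariance of 2.44 (simulated 0.171, difference 2.27). At 24 h, 2940 rose and 2641 fell in both and 690 went in opposite directions, against 1549 and 1124 for independent lists and 0 simulated. The correlation was 0.486 (simulated 0.527) and the covariance 3.08 (simulated 0.168, difference 2.91). At both times the correlation lay below its simulated value and the covariance above it. Genes are not independent replicates, and because 2 resting libraries cannot be split into groups of 2, part of the excess over independent lists may come from the shared controls.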

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

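The tests of explanations in the last 3 paragraphs of this part were chosen after the results were seen, while the interaction itself was planned. The change from 4 h to 24 h differed between co-culture and peptide, by the interaction term, for 2331 genes in the higher and 2976 in the lower direction. Its median log2 value was 4.54 for type I interferon response genes, 1.35 for interferon-gamma response genes, 2.80 for cytokines and chemokines, 1.77 for early T cell receptor response genes and -3.05 for cell cycle genes.

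Among named genes the interaction was 3.15 for Ifng, 2.89 for Tnf, 8.37 for Ccl1, 3.82 for Ido1, 3.24 for Ctla4, 8.96 for S100a8 and 0.88 for Slc3a2. It was -2.17 for Gzmb, -1.59 for Prf1, -3.05 for Il2ra, -1.87 for Tnfrsf9, -3.35 for Mki67, -9.41 for Aunip and -11.43 for Tnni2. Ccl1, S100a8, Aunip and Tnni2 were at or near 0 counts in some group, so these sizes depend on the prior count. The Tnni2 term was -2.99 (adjusted p = 0.413) without peptide 24 h replicate 2, the Ido1 term 2.48 (0.0638) without peptide 4 h replicate 2, and the Slc3a2 term 0.76 (0.0716) without co-culture 4 h replicate 1 and 0.29 (0.4) with library totals. Tnni2 also lost its call without peptide 4 h replicate 1 (0.0796) or 2 (0.0759).

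Epithelial markers were high in the co-culture libraries, with Krt8 at 1306 ± 71.1 and Krt18 at 907 ± 19.9 CPM at 4 h (SD, n = 2). Of 25 markers, 23 had all 4 co-culture libraries above the other 6. RNA of 4T1 cells left in the isolated fraction may be the source, which was not tested. Anti-CD45 beads would remove cells without CD45, but 4T1 cells bound to CTLs may have been carried along. That the CTLs themselves expressed these genes with no RNA of other cells cannot be told apart from this by the fall of T cell genes, called in 14 of 17 T cell identity genes at both times, since T cells that lose such transcripts would give the same count. No library of 4T1 cells alone was there to compare.

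Activation genes were lower in co-culture than with peptide. A lower share of CTL RNA alone would move cytokine genes as far as T cell identity genes, but at 4 h their medians were -5.53 and -1.98, a difference of -3.55 (permutation p = 0.0229 over 100000 permutations), which argues against dilution as the whole cause. For the activation receptors at 24 h the medians were -2.62 and -1.73, a difference of -0.89 (permutation p = 0.0928). Even so, 4 of 17 receptors, Tnfrsf8 (-8.32), Cd200 (-6.08), Il2ra (-5.70) and Tnfrsf9 (-4.50), lay more than 3 SE below every T cell identity gene used in the scaling, the lowest being Thy1 (-2.60). Cd200 was named after its value was seen and had only 6 and 0 counts in co-culture at 24 h. This count of receptors was also chosen after the results were seen, beside medians that did not decide, and it picks the lowest of the list. Dilution alone would not put these 4 below the T cell identity genes, but for the list as a whole the medians leave it open. The part of dilution in the lower level of other receptors was not measured. An absent T cell receptor signal in co-culture is also argued against, because 8 of 22 cytokine genes rose at 4 h against rest and fell again by 24 h with both scalings (10 by the main scaling), although some of them may come from 4T1 cells. A weaker or shorter signal in co-culture was not tested.

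B cell markers were high in the peptide libraries, with Cd79a at 45.5 ± 3.62 and Ighm at 184 ± 5.02 CPM at 4 h (SD, n = 2). All 13 of 13 markers had the 4 peptide libraries above the other 6. RNA of irradiated spleen cells carried into these libraries may be the source. B cells carry CD45, so the bead step would not remove them. Spleen cells would bring myeloid RNA too, and 4 of 14 myeloid markers split the libraries in the same way. That number cannot decide, because some markers had counts without peptide. Lyz2 had 595 and 451 at rest, and Cd14 had 201 to 304 in co-culture. Against rest, the 14 had a median log2 fold change of 3.11 with peptide at 4 h and 2.11 at 24 h, the latter 1.33 at the bounds. Xist, picked after its values were seen, had 305 to 496 counts in the 4 peptide libraries and 1 to 15 in the other 6. No biological explanation was tested, and whether spleen cells were in the peptide cultures is not given in the sources used here.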

How the results depend on the processing

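The T cell identity scaling was chosen after the data were seen, and the other settings here were planned. The totals of genes changed stayed within 1.5 times of the first value with DESeq2, DESeq2 size factors, library totals, both filters, only the groups compared and the replicate block (8427 with the block for peptide at 4 h against rest). Correlations of replicate differences between groups ran from -0.58 to 0.474, with 4 of 10 over 0.1, so whether replicate numbers pair the libraries is open. They were positive only among groups with GC correlations of one sign. Of 249 named gene results, 249 kept direction and call with DESeq2 size factors and with the block. Over all planned settings other than leave-one-out and glmTreat, 1729 values kept both, 2 lost and 5 gained a call and 3 changed sign. The named results were not counted under glmTreat, which lowered the totals of genes changed. Over leave-one-out fits, where a lone library is assumed to vary like the other groups, 3 values changed sign. With T cell identity scaling 218 kept both, 8 lost and 3 gained a call and 20 changed sign.

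With glmTreat the totals were 4562, 3545, 4664 and 5378 against rest for peptide at 4 h and 24 h and co-culture at 4 h and 24 h, 4604 and 3606 for co-culture against peptide at 4 h and 24 h, 3196 and 306 for 24 h against 4 h with peptide and in co-culture, and 1876 for the interaction. Shared genes were 905 higher and 971 lower at 4 h, and 1187 and 906 at 24 h. These are lower by construction, as the test asks for more than a 2-fold change. With T cell identity scaling the totals were 11885 for co-culture against peptide at 24 h and 10993 for 24 h against 4 h of co-culture, and shared genes were 771 lower at 4 h and 7954 higher and 128 lower at 24 h. Leave-one-out totals for 24 h against 4 h of co-culture ran from 848 (without co-culture 4 h replicate 2) to 2785 (without co-culture 24 h replicate 1), against 2433, with 1189 without co-culture 4 h replicate 1 and 1322 without co-culture 24 h replicate 2, and the cause was not tested.

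Signs that turned with T cell identity scaling were, against rest, Tnf with peptide at 24 h (0.34), Gzmb (0.98) and Prf1 (1.14) in co-culture at 4 h, and Mx1 (1.01), Gzmb (0.71), Il2ra (0.42) and Tnfrsf9 (0.65) at 24 h. In co-culture against peptide they were Slc7a5 (0.15), Slc3a2 (0.26) and Prf1 (0.16) at 4 h, and Slc7a5 (0.21), Slc3a2 (1.00) and Mki67 (1.30) at 24 h. From 4 h to 24 h they were Slc7a5 (0.96), Slc3a2 (0.0467) and Prf1 (0.28) with peptide, and Slc7a5 (1.02), Slc3a2 (0.79), Krt8 (0.75) and Epcam (1.03) in co-culture. Library totals turned Slc7a5 from 4 h to 24 h with peptide to 0.14 and its interaction to -0.38, and the 1 CPM minimum turned Ifng in co-culture at 4 h against rest to -0.0167, none of them past the threshold in the first fit. For all these signs the cause was not tested.

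Leave-one-out values ran from -0.0478 (without resting replicate 1) to 0.13 for that Ifng value, from -0.73 (without co-culture 24 h replicate 1, adjusted p = 0.0423) to 0.15 (without replicate 2) for Slc7a5 from 4 h to 24 h of co-culture, and from -0.31 (without co-culture 24 h replicate 1) to 0.57 for the Slc7a5 interaction, and the cause was not tested. Of 261 list tests 132 passed, 16 with an estimated correlation, 202 with fry (131 of the 132 among them), 130 with the block, 131 with library totals, 129 with DESeq2 size factors and 147 with T cell identity scaling, of which 112 were among the 132 and 35 were new, so 20 were lost. Of those 20, 3 pointed the other way, such as ribosome biogenesis from 4 h to 24 h of co-culture (adjusted p = 0.951).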

Other observations

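Xist and the genes high in 1 library only were chosen after their values were seen, and no explanation was tested for any gene of this part. Class II genes of antigen presentation were low at rest and in co-culture at 4 h and high in co-culture at 24 h. H2-Aa averaged 0.370 ± 0.427 CPM at rest, 28.7 ± 2.78 and 16.2 ± 7.24 CPM with peptide at 4 h and 24 h, and 0.249 ± 0.0950 and 24.8 ± 3.15 CPM in co-culture (SD, n = 2).

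Xist, the RNA that silences an X chromosome, was present in the peptide libraries and close to absent in the others. It averaged 34.6 CPM with peptide at 4 h and 21.7 CPM at 24 h, against 0.592 CPM at rest and 0.34 and 0.10 CPM in co-culture at 4 h and 24 h. Co-culture was below peptide by log2 fold changes of -6.66 ± 0.43, adjusted p = 3.3e-08 at 4 h and -7.69 ± 0.51, adjusted p = 4.2e-08 at 24 h, and below it in both libraries of each group.

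Skeletal muscle genes were among those far higher in peptide 24 h replicate 2 than in other libraries. Acta1, skeletal muscle actin, stood at 339.8 CPM there and at 1.01 CPM in replicate 1, and Myh1, a fast myosin heavy chain, at 131.0 and 0.373 CPM. Of all 35275 genes, 39 at 5 CPM or more were over 20 times higher in replicate 2 than in any other library, and 0 in replicate 1. Only 10 of them had enough counts to be tested. The 39 also included Atp2a1, Tpm2 and Ryr1, and the collagen genes Col3a1 and Col1a1 (30.0 and 18.6 CPM), so not muscle genes only.

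Some lists were not described above. Glycolysis genes passed the list test only from 4 h to 24 h of co-culture, with 5 fallen and 1 risen of 21 (2 up and 8 down adjusted over the list alone; camera adjusted p = 0.0182, and adjusted p = 0.263 with an estimated correlation), but 17 risen and 1 fallen with T cell identity scaling. CD4 T cell and NK cell markers passed only in co-culture against peptide at 4 h, with 5 lower and 1 higher of 7 (1 up and 5 down adjusted over the list alone; camera adjusted p = 0.0247, and adjusted p = 0.245 with an estimated correlation), and 4 and 2 with T cell identity scaling. The p53 and apoptosis genes (lowest camera adjusted p = 0.066) and the erythroid and platelet markers (0.334) passed in no comparison.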
